A study of Mus musculus with 9 samples.

How the data were processed

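The series holds 9 one-colour microarrays of total RNA from 3T3-L1 cells, a mouse fibroblast line that can differentiate into adipocytes. Per the labels, the cells were preadipocytes, grown with 10% fetal bovine serum and then starved of serum for 48 h. Each treated culture then received X-1 or X-3, both described in the series title as mangiferin derivatives, at 70 µM for 24 h. There were 3 groups, untreated control, X-1 and X-3, with 3 arrays each, taken from the labels. The series design text says that 9 independent experiments were done. Per the labels' protocols, RNA was purified on columns with a DNase step, and 0.5 µg was amplified and labelled with Cy3.

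The deposited scanner files hold spot intensity values, 1 file per array. Per the file headers, the intensity values were read with Agilent Feature Extraction, which subtracted background and removed spatial trends within each array and replaced low values by a surrogate. No scaling between arrays had been applied to these values. The headers name version 10.5.1.1 for replicate 1 and version 10.7.3.1 for replicates 2 and 3, while the submitters' processing notes name version 9.1. The deposited series table holds a score for each probe and array. Its scale was read from the values: each column had mean 0, SD 1 and median −0.12, and all columns shared 1 distribution. The scores therefore were quantile normalized between arrays and then standardized within each array, and genes were not centred. Within an array, 1 score unit stood for 3.96 to 4.25 log2 units of intensity, and the scores correlated with the log2 intensity across probes at r of 0.998 or more. The deposited scores were used only as an alternative. The genome build used for the expression values was not given in the sources used here.

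Same-numbered replicates lay on the same slide. Slide 1 was scanned on another day than slides 2 and 3, with the earlier software version and without spike-in RNA. On every slide the control was at position 1, X-1 at position 2 and X-3 at position 3, so position and group cannot be told apart. Whether the replicate numbers pair the arrays was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. For X-1 and control these correlations were 0.517, 0.318 and 0.271 in replicates 1, 2 and 3. For X-3 and control they were 0.238, 0.112 and 0.230. All were positive, so same-numbered arrays tended to deviate together against control, though only weakly for X-3. The deviations within a group cancel out, so these correlations are not independent. A difference of slide 1 from the other slides could by itself make all of them positive. For X-3 and X-1 the correlations were −0.041, −0.182 and 0.156, so in that comparison the deviations did not pair by number, although the slide was shared.

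Each array had 43379 spots for genes, of which 0 were saturated and between 57.9% and 67.1% were well above background by the software's own test. Replicate spots were averaged for 245 probes. Of 41174 probes, 214 were left out because every spot was marked as an outlier on at least 1 array, which left 40960. Probes were named by transcript accession (24982), gene symbol (6296) or synonym (1624) in the reference gene table, and 8058 could not be matched and kept the name the files gave. Gene names in the files of replicate 1 were carried to the other files by probe. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 25288 probes. Each gene was then represented by its brightest kept probe, which gave 16736 genes or unnamed features: 13558 with a reference symbol and 3178 without. More than 1 kept probe was available for 5918 of them.

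The log2 processed intensity of each array was reduced by that array's 75th percentile of log2 intensity over gene probes. Differences were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in 1 fit to all 9 arrays with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 16736 genes, with a threshold of 0.05. They measure the spread between samples. Errors of log2 differences are standard errors from that fit, with 3 arrays per group, and intervals are 95% confidence intervals. A gene whose group was above background on 0 of 3 arrays has no measured level there, so its fold is given as a bound, beside the adjusted p of the fit. On each of those arrays the lowest normalized signal that the software called well above background served as a floor. The bound was computed against the group mean of the gene's own signal or the floor, whichever was larger on each array.

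The gene lists, the tests, the rule for naming genes and the first set of alternative settings were fixed before the data were examined. In each comparison 41 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, and the 123 list tests were adjusted together. Camera was run again with an estimated correlation, and fry was run beside it. Members were counted as higher, lower or not called with adjustment over all genes, and also adjusted over the list alone. The rule named, in each comparison, the 12 largest increases and the 12 largest decreases among genes with a symbol that passed the threshold and moved the same way in all 3 same-numbered pairs. It added up to 4 members per list with the smallest p, and 22 genes whatever their values. Of those 22, 19 could be tested; Adipoq, Slc2a4 and Cyp1a1 were on the array but too dim. A gene named by more than 1 part counts under each. The 2 compounds' effects were also correlated across genes and set beside 100 simulated draws of unchanged groups that share the control arrays.

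The first set of alternative settings was quantile normalization, median scaling, normexp background correction (offset 50), the deposited scores, no filter on dim probes, a filter on all 9 arrays, the mean of a gene's probes, the replicate number (slide) as a block with and without 2 of these normalizations, a fit to only the groups compared, a variance prior with trend and robust, array weights, and leaving out each array in turn. Normexp used the median spot signal because the mean signal was deposited for replicate 1 only. Scaling of replicates 2 and 3 to their spike-in probes, the same arrays with the 75th percentile, and the list test without X-3 replicate 1 were added after the data were seen. The workflow was tested on simulated data made from the real arrays' spread: of 50 genes changed at each size, 2% were recovered at log2 0.5, 70% at 1, 92% at 2 and 98% at 4 (with the slide as a block 2%, 58%, 90% and 98%), and 7 of 138 calls were unchanged genes. The real comparisons gave far more calls (9417, 9255 and 1765). The adjusted threshold depends on how many genes change, so these recovered shares do not give the power of the real comparisons. Of 41 lists in the simulated data the raised list was called, and so was 1 other. The raised list, hypoxia, shares genes with other lists, so the other call need not be false. The simulated noise was independent between genes and arrays and held no slide effect. It therefore tests neither the gain from a slide block nor the preset correlation of the list test. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9. A check of gene length was left out because the reference table and the array annotation used different builds.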

Results

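Messenger RNA was measured in 3T3-L1 preadipocytes left untreated or treated with X-1 or X-3, with 3 arrays in each of the 3 groups. The log2 intensity at the 75th percentile was 10.92, 10.20 and 9.94 on the control arrays, 10.66, 9.76 and 9.63 on the X-1 arrays, and 10.63, 9.66 and 9.83 on the X-3 arrays, for replicates 1, 2 and 3. At that percentile each treated array was dimmer than the control array of its slide. The first principal component held 72.9% of the variance, with controls at −98.6 to −97.4 and treated arrays at 36.6 to 58.2. The second held 10.9% and set X-3 replicate 1 (72.4) apart from X-3 replicates 2 and 3 (−20.6 and −18.0). The number of arrays limits the precision of every value. The series title gives the purpose as expression signatures for the compounds, and the comparisons ask which genes each compound changed and where the compounds differed.

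X-1 raised nearly all measured hypoxia and glycolysis genes. Egln3, an oxygen-sensing prolyl hydroxylase, rose by 6.55 ± 0.13 on the log2 scale (93.7-fold, adjusted p = 3.61e-08, n = 3 per group). Ero1a, an oxidase of the endoplasmic reticulum, rose by 5.63 ± 0.12 (adjusted p = 3.61e-08), and Higd1a by 4.30 ± 0.11 (adjusted p = 6.52e-08). Slc2a1, the glucose transporter of most cells, rose by 3.67 ± 0.22 (12.7-fold), Slc16a3, a lactate exporter, by 3.66 ± 0.15, and Pfkfb3, a regulator of glycolysis, by 3.18 ± 0.11. Of 26 hypoxia (HIF target) genes, 23 rose, 2 fell and 1 was not called, with the same counts adjusted over the list alone. Of 19 glycolysis genes, 18 rose and 1 fell, also adjusted over the list alone. The lists share 5 genes, namely Hk2, Ldha, Pdk1, Pgk1 and Slc2a1. The hypoxia list had a median of 2.75 (2.88, 2.73 and 2.74 on slides 1, 2 and 3) and the glycolysis list one of 2.54 (2.36, 2.65 and 2.49). Both passed the list test (adjusted p = 1.23e-09 and 2.84e-09), but not with the correlation estimated (adjusted p = 0.308 and 0.284 with an estimated correlation).

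Early-response, inflammatory and interferon genes also rose with X-1. Among 33 immediate early genes 27 rose, 2 fell and 4 were not called, with the same numbers adjusted over the list alone. Atf3, a stress-induced transcription factor, rose by 5.06 ± 0.12 (adjusted p = 5.27e-08), Junb by 3.33 ± 0.13, and Ereg, a ligand of the EGF receptor, by 4.95 ± 0.18, with 2.54 at its other probe. Of 32 inflammatory genes, 24 rose and 2 fell (24 and 3 adjusted over the list alone). Ptgs2, the inducible cyclooxygenase and a member of both lists, rose by 5.62 ± 0.14 (49.3-fold, adjusted p = 6.1e-08), and Il6, a cytokine, by 3.95 ± 0.18 (15.5-fold). Csf2, a cytokine too dim to measure in the controls, was at least 13.1-fold higher (adjusted p = 6.1e-08). Of 40 interferon response genes, 33 rose and 2 fell, also adjusted over the list alone. Rsad2 rose by 4.52 ± 0.26 and Oas2 by 3.17 ± 0.23, both antiviral, and Cxcl10, a chemokine, by 3.90 ± 0.17. Medians were 1.96, 1.60 and 1.36, or 1.91, 1.57 and 1.29 with dim genes at their bounds. On slides 1, 2 and 3 they were 1.65, 2.18 and 1.96 for the early genes, 1.60, 1.69 and 1.54 for the inflammatory genes and 1.26, 1.06 and 1.62 for the interferon genes. The list tests gave adjusted p = 3.39e-09, 7.21e-07 and 6.67e-07, and adjusted p = 0.284, 0.672 and 0.686 with an estimated correlation.

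Genes of cell division fell with X-1. In the mitosis list 34 of 41 genes fell and 1 rose, the same adjusted over the list alone, with a median of −1.65 (−1.76, −1.49 and −1.45 by slide). Cenpf, a kinetochore protein, fell by 3.28 ± 0.15 (adjusted p = 5.58e-07), Ube2c by 2.89 ± 0.12 and Cdc20 by 2.38 ± 0.14, both parts of the machinery that ends mitosis. In the DNA replication list 24 of 39 genes fell and 7 rose, the same adjusted over the list alone, with a median of −0.55 (−0.54, −0.33 and −0.55 by slide). Tk1, a thymidine kinase, fell by 2.02 ± 0.12 and Lig1, a DNA ligase, by 1.47 ± 0.12, whereas E2f2 rose by 1.92 ± 0.16. Cdkn1a, an inhibitor of the cell cycle, rose by 1.98 ± 0.22 (adjusted p = 6.31e-05), while Ccnd1, a G1 cyclin, fell by 2.07 ± 0.16. The p53 target list, which holds Cdkn1a, did not pass (5 of 22 rose and 6 fell, or 5 and 5 adjusted over the list alone, adjusted p = 0.964). The mitosis and replication tests gave adjusted p = 8.34e-10 and 0.0123, and adjusted p = 0.483 and 0.93 with an estimated correlation.

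Other lists passed the test with X-1 as well. Of 14 glucocorticoid receptor targets, 12 rose and 1 fell (median 1.86; 1.80, 1.90 and 1.78 by slide). They include Lcn2, which rose by 5.16 ± 0.23, and Cebpd, which rose by 3.05 ± 0.20. Of 43 NRF2 target and glutathione genes, 22 rose and 7 fell (median 0.57; 0.39, 0.80 and 0.74 by slide; −0.25 with spike-in scaling). Srxn1, an antioxidant enzyme, rose by 2.61 ± 0.13 and Abcc1, an exporter of drugs and glutathione conjugates, by 2.45 ± 0.12. Gsta2, a glutathione transferase too dim in the controls, was at least 21.3-fold higher (adjusted p = 2.74e-07). Of 17 circadian clock genes, 12 rose and 4 fell (median 1.07; 1.11, 1.05 and 1.11 by slide), with Ciart up by 5.59 ± 0.25 and Bhlhe40 by 3.10 ± 0.11. The glucocorticoid list shares Lcn2 with the inflammatory list, Dusp1 with the immediate early list, Per1 with the clock list and Mt1 and Mt2 with the metallothionein list. These counts were the same adjusted over the list alone. The 3 list tests gave adjusted p = 0.000232, 0.00603 and 0.0225. In the same order they gave adjusted p = 0.294, 0.93 and 0.686 with an estimated correlation.

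Metal response genes, mitochondrial genes and ribosomal protein genes made up the remaining lists past the test with X-1. Of 9 metallothionein and metal response genes, 6 rose and 1 fell, also adjusted over the list alone (median 1.37; 1.03, 1.68 and 1.32 by slide). Tfrc, the transferrin receptor, rose by 3.24 ± 0.15, and Mt1 by 1.87 ± 0.16, with 3.84 at its other probe. This list gave adjusted p = 0.0482, which became 0.0527 with the slide as a block and 0.0558 without X-3 replicate 1, and adjusted p = 0.521 with an estimated correlation. Of 34 oxidative phosphorylation genes, 16 fell and 18 were not called, also adjusted over the list alone (median −0.34; −0.54, −0.18 and −0.29 by slide). Ndufb5, a subunit of complex I, fell by 1.92 ± 0.12 and Sdhb, a subunit of complex II, by 1.03 ± 0.11. Their test gave adjusted p = 0.00705, and adjusted p = 0.948 with an estimated correlation. Of 44 ribosomal protein genes, 24 rose and 1 fell (30 and 1 adjusted over the list alone). Their median was 0.42, or 0.36 above the median of all genes (0.28, 0.56 and 0.42 by slide), but −0.001 with quantile normalization (adjusted p = 0.883) and −0.43 with spike-in scaling. The test gave adjusted p = 0.000893, and adjusted p = 0.93 with an estimated correlation.

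Adipocyte and lipid genes went both ways with X-1. Of 24 adipocyte differentiation genes, 12 rose and 7 fell (12 and 8 adjusted over the list alone), and the list did not pass (median 0.54, or −0.38 with spike-in scaling, adjusted p = 0.308). Fabp4, a fatty acid binding protein of adipocytes, fell by 2.84 ± 0.20 (adjusted p = 4e-06), while Dgat2, which completes triglyceride synthesis, rose by 3.49 ± 0.15 and Plin2, a lipid droplet protein, by 2.34 ± 0.12. Lpl, a lipase, rose by 0.86 ± 0.17 (adjusted p = 0.002) and Scd1, a desaturase, by 0.71 ± 0.13 (adjusted p = 0.00169), but with spike-in scaling they were at −0.20 and −0.17, and with median scaling Scd1 was no longer called (0.50). Pparg, the main regulator of adipocyte formation, fell by 0.50 ± 0.17 (adjusted p = 0.0272); its call ended without control replicate 1, control replicate 3, X-1 replicate 2 or X-1 replicate 3, with values of −0.50 to −0.47, and without the filter on dim probes. Acaca, an enzyme of fatty acid synthesis, fell by 0.85 ± 0.15 (adjusted p = 0.00113) at its brightest probe, although its 4 probes ran from −0.85 to 0.32 and their mean was not called. Not called were Cebpa (0.40 ± 0.21; called with the mean of its probes, 0.55), Cpt1a (−0.07 ± 0.18), Srebf1 (0.03 ± 0.14) and Ppargc1a (−0.47 ± 0.41, called without X-3 replicate 1), nor was Fasn (−0.34 ± 0.14, adjusted p = 0.0593, with 0.55 at its other probe). Fasn was called without X-1 replicate 2 (−0.43) or X-3 replicate 1 (−0.34). Prkaa1, a catalytic AMPK subunit, was at −0.73 ± 0.19 at its brightest probe (adjusted p = 0.00832) but at 1.97 at its other and 0.62 for their mean, and Prkaa2, above background on 1 of 3 control arrays, was at 1.09 ± 0.39 (adjusted p = 0.0378), a call that ended without control replicate 2, control replicate 3 or any 1 X-1 array (0.79 to 1.18) and with quantile normalization or normexp. Irs1, which relays insulin signals, fell by 2.58 ± 0.17, with −0.13 at its other probe. Ccl2, a chemokine, rose by 1.09 ± 0.15, Cyp1b1 by 1.31 ± 0.13 (4.12 at its other probe) and Nqo1 by 0.79 ± 0.12, none of them called with spike-in scaling (0.25, 0.39 and 0.01), and Hmox1 was not called (1.28 ± 0.90; 0.40 without control replicate 2 and 2.14 without control replicate 1).

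Across all genes, X-1 raised 4690 and lowered 4727 of 16736 (9417 in all, limma), and 5005 of these by at least 2-fold. Eid3 rose by 8.56 ± 0.24 and was above background on 2 of 3 control arrays. Igh was at least 151-fold higher at its brightest probe (adjusted p = 1.23e-07); its 3 probes ran from 4.38 to 8.75, and another of them was above background in the controls. Gipr, the receptor of a gut incretin hormone and too dim in the controls, was at least 40.8-fold higher at its brightest probe (adjusted p = 1.18e-07, with its 3 probes from 3.16 to 7.28). Among decreases Trpm5, an ion channel too dim with X-1, was at least 26.1-fold lower (adjusted p = 5.22e-07), Tmem191c fell by 5.08 ± 0.11 and Gamt, an enzyme of creatine synthesis, by 4.05 ± 0.13. Median scaling moved the median of all genes by −0.203 and gave 3127 higher and 5115 lower; spike-in scaling of replicates 2 and 3 moved it by −0.886 and gave 1559 higher and 9878 lower. The split between higher and lower calls therefore rests on the scaling, and every log2 value here is relative to the 75th percentile. The other 28 lists did not pass, and in 10 of them the test, the median and the mean differed in sign.

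**Figure D1:**
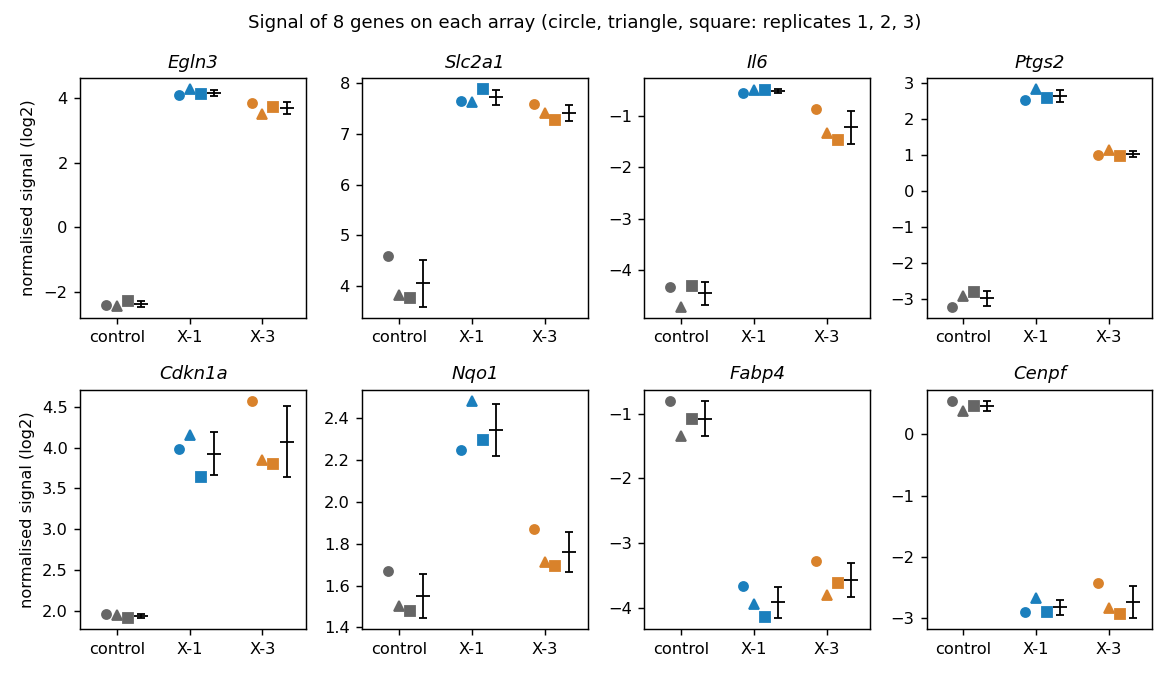
Normalized log2 intensity relative to the array's 75th percentile for Egln3, Slc2a1, Il6, Ptgs2, Cdkn1a, Nqo1, Fabp4 and Cenpf on each of the 9 arrays, with points for arrays and the mean ± SD of 3. Egln3 rose by 6.55 with X-1 and Cenpf fell by 3.28, while Nqo1, which rose by 0.79 with X-1, was at 0.01 with spike-in scaling.

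X-3 changed many of the same groups. Egln3 rose by 6.08 ± 0.13 (67.4-fold, adjusted p = 7.55e-08, n = 3 per group), Ero1a by 5.44 ± 0.12 (adjusted p = 7.55e-08), Slc16a3 by 3.91 ± 0.15 and Slc2a1 by 3.37 ± 0.22 (10.3-fold). Pfkl, a phosphofructokinase subunit, rose by 3.13 ± 0.14. Of 26 hypoxia genes 23 rose and 2 fell (23 and 3 adjusted over the list alone), with a median of 2.48 (2.70, 2.23 and 2.40 by slide). Of 19 glycolysis genes 18 rose and 1 fell, also adjusted over the list alone, with a median of 2.44 (2.48, 2.47 and 2.43 by slide). Both lists gave adjusted p = 3.1e-09, and adjusted p = 0.312 and 0.284 with an estimated correlation.

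Among 33 immediate early genes 25 rose and 2 fell with X-3, also adjusted over the list alone. Atf3 rose by 4.58 ± 0.12 and Fosl1, a partner of Jun proteins, by 3.67 ± 0.15. Of 32 inflammatory genes 24 rose and 1 fell (25 and 1 adjusted over the list alone). Ptgs2 rose by 4.02 ± 0.14 (16.2-fold, adjusted p = 3.25e-07) and Il6 by 3.24 ± 0.18 (9.47-fold), and Csf2, too dim in the controls, was at least 13.2-fold higher (adjusted p = 8.94e-08). Of 40 interferon response genes 27 rose and 3 fell, also adjusted over the list alone. Rsad2 rose by 3.42 ± 0.26 and Cxcl10 by 3.34 ± 0.17, while Ifi202b fell by 2.24 ± 0.19. The medians were 1.51 (1.42, 1.45 and 1.51 by slide), 1.45 (1.63, 1.51 and 1.25) and 0.92 (0.90, 0.83 and 1.01), and the inflammatory median was 1.39 with dim genes at their bounds. The tests gave adjusted p = 4.58e-07, 1.77e-07 and 0.000183, and adjusted p = 0.29, 0.641 and 0.868 with an estimated correlation. Of 14 glucocorticoid receptor targets 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 1.47 (1.58, 1.32 and 1.51 by slide). Lcn2 rose by 4.49 ± 0.23 and Cebpd by 2.78 ± 0.20. The test gave adjusted p = 0.00129, and adjusted p = 0.312 with an estimated correlation.

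Division genes fell with X-3 too. In the mitosis list 34 of 41 fell and 2 rose, also adjusted over the list alone. Cenpf fell by 3.19 ± 0.15, Ube2c by 2.24 ± 0.12 and Cdc20 by 2.29 ± 0.14. The median was −1.43 (−1.38, −1.60 and −1.70 by slide), with adjusted p = 8.34e-10, and adjusted p = 0.483 with an estimated correlation. The DNA replication list did not pass (6 of 39 higher and 14 lower, also adjusted over the list alone, median −0.19, adjusted p = 0.109), but did without X-3 replicate 1 (adjusted p = 0.0409). Tk1 fell by 1.74 ± 0.12, E2f1, a driver of S phase entry, rose by 1.64 ± 0.18, and Cdkn1a rose by 2.13 ± 0.22 (4.37-fold).

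Of 34 oxidative phosphorylation genes 16 fell and 18 were not called with X-3, also adjusted over the list alone, with a median of −0.45 (−0.24, −0.56 and −0.49 by slide). Ndufb5 fell by 1.64 ± 0.12 and Sdhb by 1.07 ± 0.11. The test gave adjusted p = 0.00513, and adjusted p = 0.942 with an estimated correlation. Of 44 ribosomal protein genes 20 rose and 24 were not called, also adjusted over the list alone, and Rps15 rose by 1.07 ± 0.19 (not called with spike-in scaling, 0.30). Their median was 0.40, or 0.34 above the median of all genes (0.53, 0.38 and 0.27 by slide). The test gave adjusted p = 0.000923, and adjusted p = 0.93 with an estimated correlation. That list was not called with quantile normalization (adjusted p = 0.421), and its median was −0.33 with spike-in scaling. Of 17 clock genes 10 rose and 4 fell, also adjusted over the list alone. Ciart rose by 4.75 ± 0.25 and Bhlhe40 by 2.89 ± 0.11, and the median was 0.76 (1.17, 0.54 and 0.72 by slide; −0.06 with spike-in scaling). The clock test gave adjusted p = 0.0459, which became 0.0745 with the slide as a block, and adjusted p = 0.755 with an estimated correlation.

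Fabp4 fell by 2.49 ± 0.20 with X-3 (adjusted p = 1.08e-05), whereas Dgat2 rose by 2.85 ± 0.15, Plin2 by 1.87 ± 0.12 and Cebpa, a regulator of adipocyte genes, by 1.04 ± 0.21 (adjusted p = 0.00249). The adipocyte list did not pass (11 of 24 higher and 7 lower, also adjusted over the list alone, median 0.36, or −0.40 with spike-in scaling, adjusted p = 0.352). Lpl rose by 1.00 ± 0.17 (0.05 and not called with spike-in scaling), and Cebpa was not called with spike-in scaling either (0.56). Scd1 was at 0.36 ± 0.13 (adjusted p = 0.0454), a call that ended without control replicate 2 or 3, X-1 replicate 2 or any 1 X-3 array (0.30 to 0.40) and with median scaling or normexp, and its value was −0.32 with spike-in scaling. Fasn, the fatty acid synthase, fell by 0.51 ± 0.14 at its brightest probe (adjusted p = 0.011), with 0.73 at its other and 0.11 for the mean of both. Prkaa1 was likewise at −1.03 ± 0.19 (adjusted p = 0.00141) at its brightest probe, at 1.86 at its other and at 0.41 for the mean of both. Pparg (−0.38 ± 0.17), Srebf1 (−0.20 ± 0.14) and Prkaa2 (0.85 ± 0.39) were not called, except without X-3 replicate 1, when they were at −0.57, −0.32 and 1.29. Also not called were Acaca (−0.35 ± 0.15; called without X-1 replicate 1), Ppargc1a (−0.89 ± 0.41; −0.31 without X-3 replicate 1, and −1.23 and called without X-3 replicate 2), Cpt1a (0.11 ± 0.18), Hmox1 (0.93 ± 0.90; 0.05 without control replicate 2 and 1.79 without control replicate 1) and Nqo1 (0.21 ± 0.12). Irs1 fell by 2.93 ± 0.17 (−0.46 at its other probe), Ccl2 rose by 1.09 ± 0.15 and Cyp1b1 by 0.98 ± 0.13 (3.28 at its other probe), the latter pair not called with spike-in scaling (0.24 and 0.12). Of 43 NRF2 target genes 17 rose and 11 fell, also adjusted over the list alone, and the list did not pass (median 0.25, or −0.47 with spike-in scaling, adjusted p = 0.278), although Srxn1 rose by 2.26 ± 0.13 and Abcc1 by 1.73 ± 0.12.

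In all, X-3 raised 4838 and lowered 4417 genes (9255, limma), 4548 of them by at least 2-fold. Eid3 rose by 8.09 ± 0.24 (above background on 2 of 3 control arrays), Igh was at least 174-fold higher at its brightest probe (adjusted p = 1.51e-07, with its 3 probes from 4.84 to 8.95), and Gabpb2, too dim in the controls, was at least 29.5-fold higher at its brightest probe (adjusted p = 1.97e-06, with 1.66 at its other). Tmem191c fell by 4.13 ± 0.11 and Nckap5 by 3.79 ± 0.16, and Sybu, too dim with X-3, was at least 7.18-fold lower (adjusted p = 4.44e-06). Median scaling moved the median of all genes by −0.205 and gave 3081 higher and 4875 lower; spike-in scaling moved it by −0.699 and gave 1860 higher and 8327 lower. The other 31 lists did not pass, and in 9 of them the test, the median and the mean differed in sign.

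Markers of other cell types were measured beside these groups. Of 11 macrophage and leukocyte markers, 6 were higher and 3 lower with each compound (adjusted p = 0.767 with X-1 and 0.553 with X-3). Csf1r, the receptor of a macrophage growth factor, rose by 1.11 ± 0.13 and 1.25 ± 0.13 (0.21 and 0.43, not called, with spike-in scaling). Lyz2, a lysozyme, fell with both compounds (−1.57 ± 0.13 and −1.53 ± 0.13). Of 5 epithelial markers, 3 were higher with X-1 and 4 with X-3 (adjusted p = 0.227 and 0.0754), with Krt8, a keratin, up by 1.89 ± 0.14 and 2.38 ± 0.14. The endothelial list had 2 of 5 lower with X-1, and 2 higher and 1 lower with X-3 (adjusted p = 0.758 and 0.964). Skeletal muscle markers (2 higher and 2 lower of 8, then 3 and 1) and bone and cartilage markers (3 and 3 of 10, then 3 and 2) did not pass either (adjusted p = 0.964 and 0.681, then 0.964 and 0.964).

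**Figure D2:**
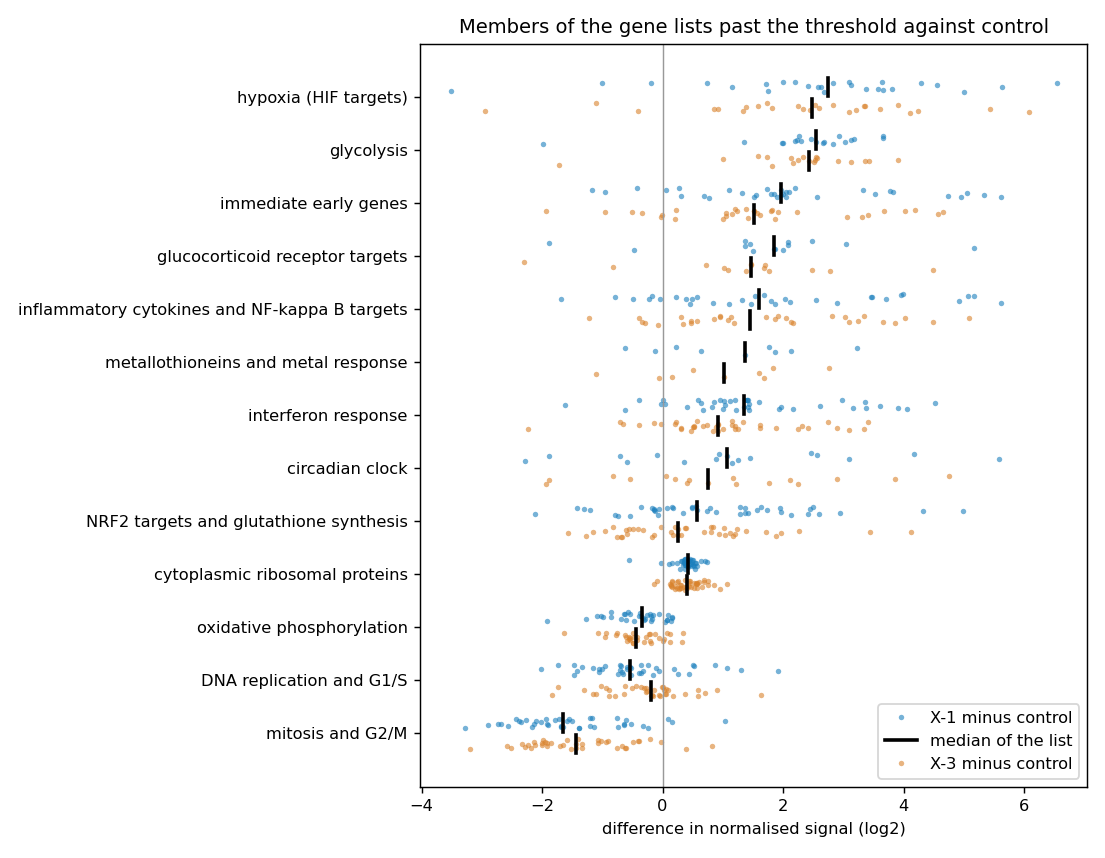
Log2 difference from control of each measured gene in 13 lists, with X-1 and X-3 side by side and black bars at the medians. The hypoxia medians were 2.75 and 2.48 and the mitosis medians −1.65 and −1.43, while the ribosomal protein medians of 0.42 and 0.40 turned to −0.43 and −0.33 with spike-in scaling, as did the NRF2 medians with X-1 (0.57 to −0.25) and X-3 (0.25 to −0.47) and the clock median with X-3 (0.76 to −0.06). That scaling moves all genes alike, and these medians stayed above the median of all genes.

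The effects of the compounds resembled each other across genes, and in the direct test of their difference at the same dose and time 6 of the 41 lists passed, each lower with X-3, but 0 with an estimated correlation (adjusted p = 0.29 to 0.686). Ptgs2 was 3.04-fold lower with X-3 than with X-1 (log2 −1.60 ± 0.14, adjusted p = 0.00401, n = 3 per group). Ereg was lower too (−1.53 ± 0.18, and −0.62 at its other probe), as was Dusp6, a phosphatase that limits ERK signalling (−1.12 ± 0.16). These genes belong to the immediate early list, of which 11 of 33 were lower and the others not called (14 lower adjusted over the list alone), with a median of −0.47 (−0.23, −0.55 and −0.48 by slide). Slc7a11, the cystine importer (−1.33 ± 0.18), Gsr, glutathione reductase (−1.15 ± 0.13), and Gsta3, a glutathione transferase (−1.25 ± 0.15), were lower in the NRF2 list, where 12 of 43 were lower and 2 higher (17 and 2 adjusted over the list alone; median −0.36; −0.12, −0.55 and −0.55 by slide).

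Of 26 hypoxia genes, 6 were lower with X-3 and 1 higher (10 and 1 adjusted over the list alone), with Adm, a vasodilator peptide, at −0.98 ± 0.14. The hypoxia median was −0.34 (−0.10, −0.58 and −0.36 by slide). Plod2, a collagen lysyl hydroxylase outside the hypoxia list, was at −1.08 ± 0.17. Of 40 interferon genes, 4 were lower (10 lower and 1 higher adjusted over the list alone; median −0.47; −0.36, −0.26 and −0.66 by slide), with Oas2 at −1.29 ± 0.23 (adjusted p = 0.013; not called without X-1 replicate 3, −1.25). Of 14 glucocorticoid targets 2 were lower (also adjusted over the list alone; median −0.37; −0.13, −0.45 and −0.43 by slide), as were 2 of 8 aryl hydrocarbon receptor targets (5 adjusted over the list alone; median −0.35; −0.10, −0.60 and −0.49 by slide), which share Gsta1 and Nqo1 with the NRF2 list. The 6 tests gave adjusted p = 1.06e-07 for immediate early genes, 3.38e-08 for NRF2 targets, 6.48e-05 for hypoxia, 7.21e-07 for interferon, 0.00705 for glucocorticoid and 0.00308 for aryl hydrocarbon receptor targets. With an estimated correlation they gave adjusted p = 0.29, 0.557, 0.557, 0.686, 0.445 and 0.445, in that order. The amino acid response and unfolded protein response lists (adjusted p = 0.067 and 0.118) did not pass, but did without X-3 replicate 1 (adjusted p = 0.0476 and 0.0122), and no other array was left out of the list test. The glycolysis (median −0.15, adjusted p = 0.167), inflammatory (1 higher and 6 lower of 32, adjusted p = 0.429) and mitosis lists (3 higher of 41, adjusted p = 0.217) did not pass. In all 35 lists did not pass, and in 8 of them the test, the median and the mean differed in sign.

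Other genes were higher with X-3 than with X-1. Cdk5, a kinase of neurons, was at 1.59 ± 0.17 (3.01-fold), Mmp2, a gelatinase, at 1.17 ± 0.14, Mmp11 at 1.07 ± 0.12, Col6a2, a collagen VI chain, at 1.08 ± 0.15 (0.18 at its other probe), and Cd34, a surface marker of progenitor cells, at 1.03 ± 0.13. E2f1 was higher (1.12 ± 0.18) and E2f2 lower (−1.33 ± 0.16). Il1rl1, the receptor of interleukin 33, was lower (−1.18 ± 0.15), as was Hspa1b, an inducible heat shock protein (−1.42 ± 0.20). Of the largest differences, Stfa3 (−2.47 ± 0.33) and Csta1 (−2.44 ± 0.38), members of a family of cysteine protease inhibitors, were lower with X-3.

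Of 16736 genes, 1167 were higher and 598 lower with X-3 than with X-1 (1765 in all, limma), 312 of them by at least 2-fold. The split was 2891 and 3530 in replicates 2 and 3 alone and 1592 and 273 there with spike-in scaling, which moved the median of all genes by 0.174. The count was 462 with median scaling, 545 without the filter on dim probes and 709 with only the groups compared. It was 3408 without X-3 replicate 1 (1711 of them shared), 1054 without control replicate 3, 583 without X-1 replicate 2, 601 without X-1 replicate 3, 728 without X-3 replicate 2 and 739 without X-3 replicate 3.

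For other genes named whatever their values the difference was not called, and a p that misses the threshold does not show that the compounds act alike. The 95% interval of X-3 minus X-1 ran from −0.33 to 0.33 for Ccl2, −0.80 to 0.20 for Slc2a1, −0.10 to 0.80 for Fabp4, −0.24 to 0.52 for Lpl, −0.25 to 0.50 for Pparg, −0.48 to 0.14 for Fasn and −2.38 to 1.69 for Hmox1. It ran from 0.17 to 1.11 for Cebpa (adjusted p = 0.0844; 0.77 and called without X-3 replicate 1), from 0.16 to 0.85 for Acaca (adjusted p = 0.067; 0.66 and called without X-1 replicate 1), and from −0.65 to −0.04 for Scd1 (adjusted p = 0.138). Il6 was lower with X-3 (−0.71 ± 0.18, adjusted p = 0.0398), but its call ended without control replicate 3, any 1 X-1 array, X-3 replicate 2 or X-3 replicate 3 (−0.73 to −0.59) and with median scaling, normexp or spike-in scaling. Nqo1 was lower too (−0.58 ± 0.12, adjusted p = 0.0206), and its call ended without X-1 replicate 2 or 3 or X-3 replicate 2 or 3 (−0.61 to −0.51) and with the same scalings.

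**Figure D3:**
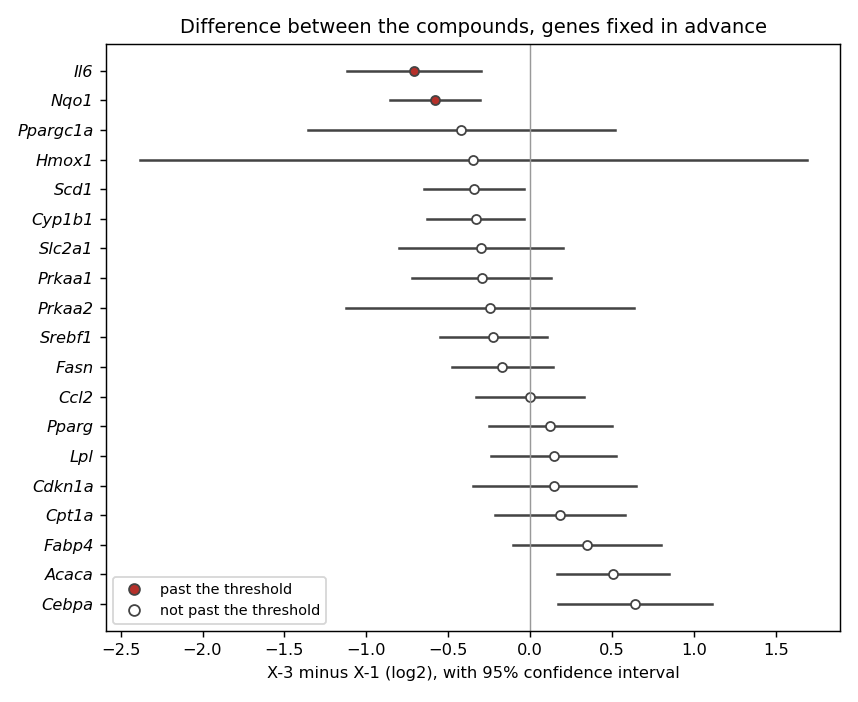
Log2 difference X-3 minus X-1 with its 95% confidence interval for the 19 genes named whatever their values. The interval excluded 0 for 6 of them, including Il6 and Nqo1, and included 0 for 13.

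Across the 16736 genes, the log2 differences from control of the compounds correlated at r = 0.934 (rho 0.909), and within slides 1, 2 and 3 at r = 0.815, 0.900 and 0.906; genes are not independent replicates. Simulated unchanged groups sharing the control arrays gave r = 0.501 and a covariance of 0.0315, against a measured covariance of 1.25, a difference of 1.21. The simulated noise was independent between arrays and held no deviation shared within a slide. Genes such as Egln3 and Ptgs2 were among 3869 higher with both compounds (1356 expected if calls were independent), and Cenpf and Fabp4 were among 3770 lower with both (1248 expected). Part of the excess over the expected counts may come from the 3 shared controls, which cannot be split. Among 894 genes called in the same direction with both and also called different between them, 671, Ptgs2 among them, moved further with X-1 and 223 further with X-3.

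**Figure D4:**
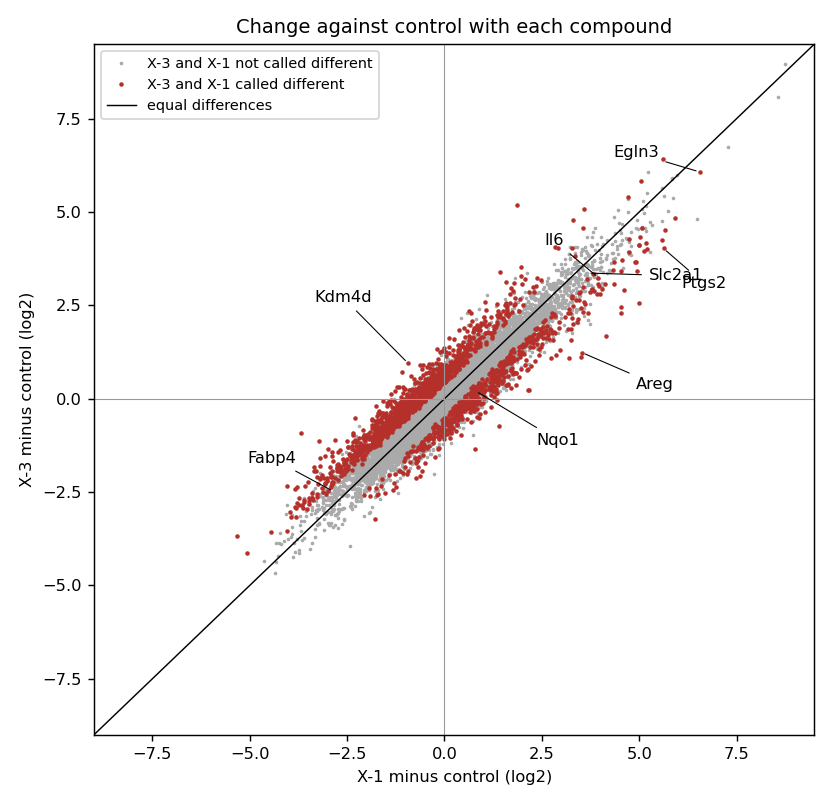
Log2 difference from control with X-3 against that with X-1 for 16736 genes, with genes called different between the compounds in red. The points follow a line with r = 0.934, and 28 genes were called in opposite directions (218 in replicates 2 and 3 alone).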

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

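All tests of the spike-in pattern were chosen after the result was seen, while the counts over other splits of the arrays were planned. Synthetic E1A RNA, a set of transcripts added to each sample as a technical standard, was outside the comparisons and stood out because its signal was higher on treated arrays than on the control of their slide. Relative to the array's 75th percentile, the mean log2 signal of the 8 usable spike-in probes was set against that of the control of the slide. The difference was 0.675 for X-1 replicate 2, 1.107 for X-1 replicate 3, 0.862 for X-3 replicate 2 and 0.524 for X-3 replicate 3. On each of these arrays 8 of 8 probes were higher. Slide 1 carried no spike-in RNA. With median scaling the smallest of the 4 differences was still 0.251. That argues against a shift of the 75th percentile alone as the whole cause. A fall in the whole signal of an array would move both measures, so median scaling cannot test it. Unequal amounts of spike-in RNA added per array could account for the pattern and cannot be told apart from the groups: of the 15 splits of these 6 arrays into 4 and 2, only the real one (count 1) gave a difference as large, with 0.426 the highest of the others, too few for a share under 0.05. A lower share of messenger RNA in the total RNA of treated cells, which the treatment groups allow, stays open and untested.

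The planned count of genes past the threshold was repeated over the 10 splits of each pair of groups into 3 and 3, which are too few for a share under 0.05. In each comparison 1 split, the real one, gave a count as large. The real counts were 9417 for X-1 against control, 9255 for X-3 against control and 1765 for X-3 against X-1, and the highest among the other splits were 0, 0 and 1. Against control, where same-numbered arrays tended to deviate together, the other splits that parted all 3 slides also gave at most 0. All the other splits differ from the real one in mixing arrays of the groups compared. A real difference then widens the spread within their groups, so low counts there were likely in any case. They do not show how many calls would arise without an effect.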

How the results depend on the processing

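The scaling to spike-in probes, its companion on replicates 2 and 3 alone and the list test without X-3 replicate 1 were chosen after the data were seen. The counts against control kept within 1.5 times of 9417 and 9255 under every alternative run (leaving out single arrays gave 8237 to 10922 with X-1 and 7970 to 10492 with X-3), and the correlation of the compounds stayed between 0.888 and 0.935. The count for X-3 against X-1 did not: it was 462 with median scaling, 1049 with normexp, 545 without the filter on dim probes, 725 with the replicate block and normexp, 709 with only the groups compared, 6753 with array weights (X-3 replicate 1 had weight 0.109), 6421 in replicates 2 and 3 alone, and 583 to 3408 when single arrays were left out; the cause was not tested. With an estimated correlation 0, 0 and 0 lists passed in the 3 comparisons (camera; 4, 5 and 3 at an unadjusted p under 0.05), against 13, 10 and 6 with the preset one, while fry, which does not compare a list with other genes, called 25, 27 and 9. With the slide as a block 9954, 9736 and 1728 genes and 12, 9 and 6 lists passed, and 556 of 580 results on named genes kept their call; for the genes and lists described against control it changed no call but those of the metallothionein and clock lists. Of the named-gene results 312, and of the 123 list results 89, were the same in every alternative. None of those stable list results had passed, since all 29 list results that passed lost their call with an estimated correlation. Spike-in scaling, which moves all genes alike, ended 89 named-gene calls and turned the direction of 21 results. Against control it kept a similar count but not the same genes. Of its 11437 calls with X-1, 6269 were among the 9417, and of its 10187 with X-3, 6083 were among the 9255. The same arrays with the 75th percentile shared 9209 and 8965. The replicate block with normexp ended 89 named-gene calls, and array weights added the most (76). Signal over background limits the dim genes, for which only bounds are given.

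Direction turned for some genes. With spike-in scaling this follows from the common shift of all genes (their median moved by −0.886 with X-1 and −0.699 with X-3) and shows nothing particular to a gene, except that Cpt1a with X-3 was at −0.152 in replicates 2 and 3 without it. The X-1 values there were −0.389 for Cldn3, −0.122 for Fbl, −0.243 for Krt14, −0.202 for Lpl, −0.477 for Nr1h2, −0.288 for Rps4x, −0.035 for Rps6, −0.184 for Rps7, −0.198 for Rps9, −0.167 for Scd1, −0.011 for Sox9, −0.76 for Srebf1 and −0.016 for Tnnc2. The X-3 values there were −0.107 for Abca1, −0.845 for Cpt1a, −0.117 for Esam, −0.258 for Myh1, −0.144 for Nip7, −0.002 for Pes1, −0.317 for Scd1 and −0.018 for Sost. With the mean of a gene's probes the direction turned because another probe of the gene went against its brightest one. Why the probes differ was not tested. The X-1 values with that mean were 0.618 for Prkaa1, −0.319 for Rps6 and 0.048 for Uvrag. The X-3 values were −0.003 for Cab39, 0.108 for Fasn, −0.417 for Pes1, 0.412 for Prkaa1, −0.21 for Rps6 and 0.282 for Uvrag, and X-3 minus X-1 was −0.038 for Atg7.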

Other observations

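The tests of X-3 replicate 1 for a wrong label and for its slide were chosen after the result was seen, and the genes called in opposite directions were named after their values were seen.

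A small set of genes moved in opposite directions with the compounds. Of the 28, 25 have a symbol. Kdm4d, a histone demethylase, fell by 0.94 with X-1 (adjusted p = 0.00182) and rose by 0.95 with X-3 (adjusted p = 0.00183), with 3 arrays per group. Retsat, a retinol saturase of adipose tissue, fell by 0.78 with X-1 and rose by 0.54 with X-3 (adjusted p = 0.00109 and 0.0088), and Mmp2 fell by 0.54 and rose by 0.63 (adjusted p = 0.00849 and 0.00411). Nav3 went the other way, up by 0.90 and down (−0.53), as did Id4, an inhibitor of differentiation factors, up by 0.67 and down (−0.62), and Ogt, which adds GlcNAc to proteins, up by 0.58 and down (−0.55). These signs rest on the 75th percentile, since spike-in scaling moved the median of all genes by −0.886 with X-1 and −0.699 with X-3. The difference between the compounds was called for Kdm4d (1.89 ± 0.18) and Mmp2 (1.17 ± 0.14). In addition, 69 genes were called different between the compounds and against control with neither.

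X-3 replicate 1 lay apart from X-3 replicates 2 and 3, which correlated with each other across genes at 0.997 and with it at 0.975 or less. Its correlations with X-1 replicates 1, 2 and 3 were of the same size (0.975, 0.977 and 0.973). Malat1, a nuclear RNA, was at −3.72 in X-3 replicate 1 against the mean of the other X-3 arrays. Features without a gene symbol were lower there by over 1 log2 unit in 25.0% of cases (794 of 3178), against 4.46% of named genes (604). An X-1 sample under a wrong label stays open: on the 6421 genes called between the compounds in replicates 2 and 3 alone, along their axis from X-1 (0) to X-3 (1), it lay 0.176 from X-1 replicate 1, and other arrays' deviations, scaled to its own, reached 0.518, while of the 218 genes called there in opposite directions against control, 124 lay on the X-3 side of the control in it and 64 in X-1 replicate 1. Of the 666 genes at least 2-fold apart there, 73.7% differed from X-1 replicate 1 in the direction of X-3, which leans against a wrong label, but only 54.5% of the 191 on which X-3 lay on the side of X-1 away from control. Its deviation correlated at 0.238 and −0.041 with those of control and X-1 on the same slide. The tables therefore argue against the slide or scan day as the whole cause of its position, but not against a part. A lower share of nuclear and unspliced RNA in this sample may account for its position. The 4 nuclear RNAs other than Malat1 had a median of −0.074 with an SD of 0.746. By the prediction written beforehand, that median counts against this explanation. Neat1 (−0.157), Tug1 (0.338) and Kcnq1ot1 (0.008) lay near the other X-3 arrays, but Airn was at −1.371. With so few genes and that spread the question stays undecided, and no biological explanation was tested.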
